A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

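RNA was extracted with hot phenol and sequenced from 12 yeast libraries made with a directional kit, in 6 groups of 2 libraries, as listed in the labels. Groups were taken from the titles of the samples. The design (tests, groups, gene lists, alternatives and the rule for naming genes) was fixed before the data were examined, and later choices are marked as such where they appear.

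The authors trimmed the reads with Trim Galore, checked them with FastQC and aligned them with HISAT2, per the submitters' processing notes, which give no versions. The read counter, the strand counted and the genome build are not given in the sources used here, so no coordinates are printed. Differential expression was computed by the authors with DESeq2 1.34.0, per the submitters' processing notes. For each of 5 comparisons the authors deposited a table of normalized counts, a signal equal to the reads of a transcript divided by the DESeq2 size factor of the library within that table. The deposited log2 fold changes and their standard errors were computed by the authors with DESeq2 between the groups of each table. The deposited p-values and q-values are those of the authors' DESeq2 test, and the q-values are Benjamini-Hochberg adjusted. The number of transcripts in each class was deposited with the authors' limits of 0.5 and -0.5 in log2 fold change, 0.05 in p and 0.01 in q.

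Whole reads were recovered from the deposited values by dividing by the value of 1 read in each library. All values (100.0%) were whole within 0.01 reads, and for the 8 libraries that occur in 2 tables the recovered reads of 0 transcripts differed. Transcripts were matched to gene names in the table of the reference annotation: 5944 of 5970 by RefSeq accession, 26 by locus tag, and 0 remained unmatched. Of these, 3 transcripts with no entry in the authors' comparison sheets are not reported here, which left 5967. The total per library was 14110933 to 18363356 reads, and the 10 most abundant transcripts held 9.12 to 15.4% of them.

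Tests stayed within a table, since tables were normalized separately. Transcripts with a mean normalized value of at least 10 over the 4 libraries compared were tested with limma 3.58.1 in R 4.3.3, using eBayes with an intensity trend on log2 of the value plus 1, and called at a Benjamini-Hochberg adjusted p under 0.05. The design allowed an edgeR fit of all libraries had raw counts been given. The tables held normalized values, so limma was used throughout and the count tests became alternatives. The different perchlorate response of the mutant was tested as an interaction over the 8 libraries of both treatment tables, each difference taken within its own table. Overlaps of calls were set against n1 × n2 / N, and correlations were computed across genes. For 26 gene lists the members passing over all genes and over the list alone were counted. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 and again with an estimated one. The estimated version rests on the residual degrees of freedom of the fit, 2 in each comparison and 4 in the interaction. With so few, a list that did not pass is not shown to be unchanged. Low counts were compared as ratios of recovered reads with exact 95% counting intervals, and a count of 0 was replaced by a limit of 3 reads per library.

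Genes were named by a rule. It took EDC3, LSM4 and the strain markers where genotypes were compared. It took the 8 largest rises and the 8 largest falls among called genes whose groups did not overlap and whose mean was at least 50 (6 per direction for the interaction). From each list described it took up to 3 called members with the largest change, or the member with the smallest p. Members outside this rule were named only where a list count was 5 or fewer, or to describe the interaction or the strain difference. They were chosen after their values were seen, and most were not refitted under the alternatives. Near-identical copies (at least 95% identity over at least 50% of the transcript) were found for 274 transcripts, and 178 overlap another gene by at least 50 bases; such genes are called uncertain.

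The tests were tried on simulated reads with 200 changed genes, drawn from those with a mean of at least 50 reads and changed by at least 2-fold. The recovery rates therefore do not cover smaller changes or genes with lower means. With limma, 2-fold changes were recovered for 95% of the changed genes in WT with perchlorate, 98% in the mutant with perchlorate, 98% between untreated strains, 97% between strains in perchlorate, 92% for shock and 77% for the interaction. Over these, 3.94 to 6.35% of calls were false. With edgeR 4.0.16 and DESeq2 1.42.0, 94% and 92% were recovered in WT with perchlorate, with 7.18% and 8.57% of calls false. In a simulated shift of 0.5 log2 in the proteasome list, camera found that list and no other of the 24 lists tested. The simulated genes varied independently, so false list calls caused by correlated genes could not arise there.

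Alternatives were median-of-ratios and upper-quartile rescaling, no filter and a minimum mean of 50, pseudocounts of 0.5 and 5, eBayes without the trend and with robust estimation, edgeR and DESeq2 on the recovered reads of 12 libraries, a 2-fold minimum, each library left out in turn, the replicate number as a block, and the genotype tables in place of the treatment tables for the interaction. Alternatives chosen after seeing the data were untreated WT as the control for shock, and the genotype comparisons without absent, mating type and marker genes. Rescaling moved the median log2 fold change by at most 0.0320 log2 in any comparison. RT-qPCR mentioned in the series text was not analysed here.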

Results

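Transcript levels were measured by RNA sequencing in 12 libraries of the budding yeast Saccharomyces cerevisiae, in 6 groups of 2 libraries. The wild type (WT) was BY4741, a haploid laboratory strain of the a mating type that is known to lack LEU2 and MET17. The mutant lacked EDC3 and the C-terminal domain of Lsm4, proteins that help assemble P-bodies, the cytoplasmic condensates of untranslated mRNA and decay factors. Both strains were grown untreated or with 100 mM sodium perchlorate, a salt found in Martian soil, in medium without uracil at 30 °C. The remaining WT cells were either exposed to a shock wave of 5.6 Mach and regrown, or left unshocked. All cultures were harvested at an OD600 between 0.4 and 0.5. The libraries held 14110933 to 18363356 reads on transcripts and detected 5874 to 5898 transcripts each. Replicates of a group had a Pearson r of 0.986 to 0.995 across genes, which are not independent replicates. Their counts differed beyond sampling noise, with a chi-square of 16.9 to 38.2 times its degrees of freedom. No pair was therefore a single library deposited more than once. The labels do not say that replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. Normalized reads come from 1 table per comparison, and these tables were normalized separately.

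The deleted gene and the strain markers were examined first. EDC3 (YEL015W), an enhancer of mRNA decapping, had 1 to 4 reads in each mutant library and 745 to 1365 reads in each WT library. The mutant-to-WT ratio of EDC3 was 0.00365 in untreated cells (95% counting interval 0.00134 to 0.00796) and 0.00116 in perchlorate (0.000141 to 0.00421). Such intervals, and limits set by a count of 0, cover counting error only. LSM4 (YER112W) did not pass the test between genotypes, with a log2 fold change of -0.08 ± 0.16 (SE; adjusted p = 0.748) in untreated cells and 0.24 ± 0.11 (adjusted p = 0.109) in perchlorate. Without WT untreated replicate 2 the value of LSM4 in untreated cells was 0.11 (adjusted p = 0.551). A count over the whole transcript does not test the removal of the C-terminal domain. The strains also differed in markers other than the mutated genes. LEU2 and MET17, which encode enzymes of leucine and methionine synthesis, had 0 reads in both untreated WT libraries. They were at least 1914-fold and 3094-fold higher in the untreated mutant, against a limit of 3 reads per library. Of transcripts specific to a cells, MFA1, which encodes the a-factor pheromone, had 6 to 13 reads per mutant library and 776 to 5490 per WT library, and STE6, which encodes the a-factor exporter, 227 to 271 and 1843 to 7667. Of those specific to alpha cells, MF(ALPHA)1, which encodes alpha factor, had 6140 to 22817 reads per mutant library and 4 to 111 per WT library. The alpha agglutinin gene SAG1 had 792 and 1157 reads in the untreated mutant against 438 and 433 in untreated WT, but 435 and 400 against 647 and 522 in perchlorate.

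**Figure D1:**
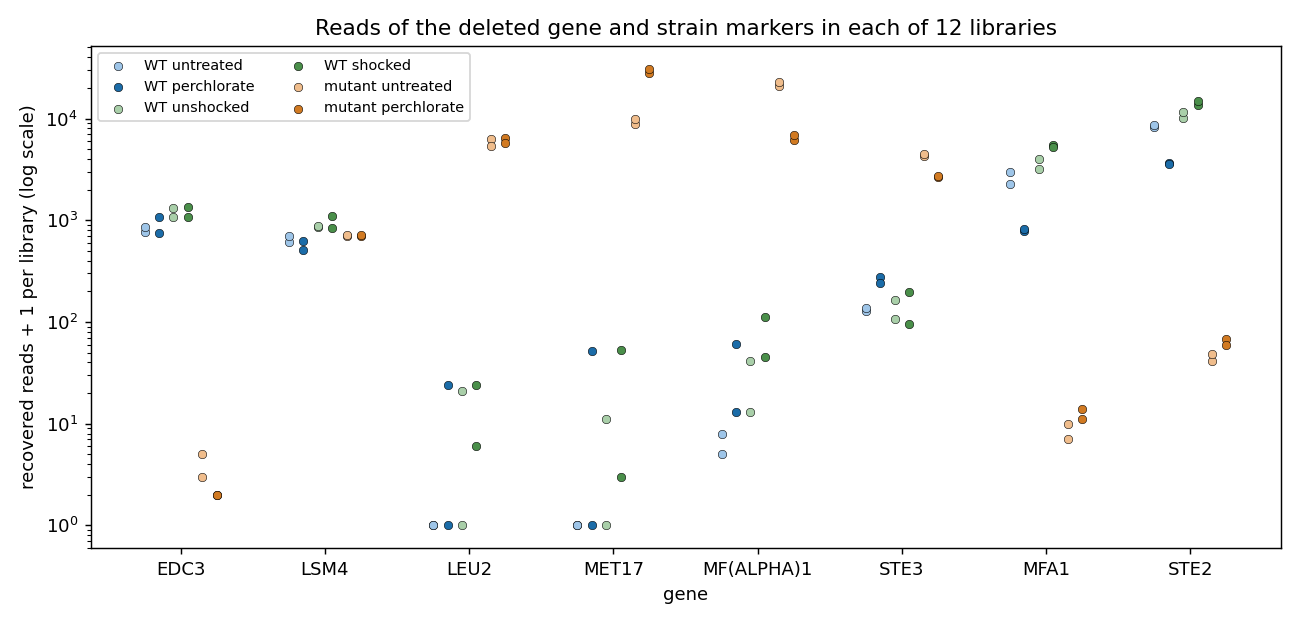
Recovered reads per library plus 1, on a log axis, for the deleted gene EDC3, for LSM4 and for strain and mating type markers; each point is 1 library, coloured by group. Mutant libraries sit at 1 to 4 reads of EDC3, and WT libraries at 745 to 1365.

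The comparison of perchlorate-grown with untreated WT asked which transcripts respond to continuous growth in the salt. Genes of the osmotic and general stress responses were among those that rose most. STL1 (YDR536W), a glycerol transporter of the plasma membrane, went from 11.3 ± 1.69 to 751 ± 2.42 normalized reads (mean ± SD, n = 2), and its read ratio was 72.9 (95% counting interval 47.5 to 118). GRE1 (YPL223C), a hydrophilin made under dehydration, rose from 169 ± 42.0 to 8199.7 ± 1604 normalized reads, a log2 fold change of 5.60 ± 0.20 (SE; adjusted p = 2.48e-07). In the Msn2/4 general stress list 34 of 41 tested members rose and 0 fell, or 39 and 0 adjusted over the list alone. Among them were TKL2 (YBR117C), a transketolase, at 4.82 ± 0.19, NQM1 (YGR043C), a transaldolase, at 4.41 ± 0.23 and the aldehyde dehydrogenase gene ALD3 at 4.11 ± 0.23. In the Hog1 osmotic list 15 of 32 tested members rose and 0 fell, or 15 and 0 adjusted over the list alone. Of 24 lists tested with camera at a preset correlation of 0.01, 15 passed in WT. With an estimated correlation none did (adjusted p = 0.464 to 0.561 for those 15), but that test had only 2 residual degrees of freedom. At the other end, IMD2 (YHR216W), an IMP dehydrogenase of GTP synthesis, fell by 3.06 ± 0.20 on the log2 scale (adjusted p = 8.59e-06). The purine enzyme ADE17 (YMR120C) followed at -2.44 ± 0.15 and the flavohemoglobin YHB1 (YGR234W) at -2.40 ± 0.17.

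Metabolic groups moved in both directions in WT. Among respiratory chain and ATP synthase genes 36 of 40 tested members rose and 0 fell, or 37 and 0 adjusted over the list alone. The NADH dehydrogenase gene NDE2 led them at 2.56 ± 0.29. The malate synthase gene MLS1 of the glyoxylate cycle rose by 2.99 ± 0.22 and the gluconeogenic PCK1 by 2.60 ± 0.17. In the glycolysis list 4 of 24 tested members rose (PDC6, ENO1, TDH1, ADH2) and 6 fell, or 4 and 9 adjusted over the list alone, and ENO1 stood at 1.48 ± 0.16. HXT5, which encodes a transporter of slow-growing cells, rose by 4.31 ± 0.33, while in the whole hexose transport list 1 of 16 tested members rose (HXT5) and 1 fell (MIG2), or 1 and 0 adjusted over the list alone, with a median of -0.07, a mean of 0.36 and an upward direction in camera, which did not pass (adjusted p = 0.878). In the sulfur assimilation and methionine list 16 of 33 tested members rose and 2 fell (HOM2, SAM3), or 17 and 3 adjusted over the list alone. The sulfate permease gene SUL2 was at 2.06 ± 0.15 and the homoserine acetyltransferase gene MET2 at 2.11 ± 0.14. The Gcn4 amino acid list moved the other way: 28 of 56 tested members fell and 2 rose (SER33, CPA1), or 33 and 2 adjusted over the list alone. HIS4 was at -2.02 ± 0.14, LEU1 at -1.75 ± 0.13 and BAT1 at -1.31 ± 0.13. Phosphate starvation genes gave 2.33 ± 0.28 for the phosphatase PHM8 and 1.76 ± 0.21 for the transporter PHO89, and 5 of 23 tested members rose (uncertain PHO84, PHM8, PHO89, PHO5, PHO8) and 2 fell (PHO3, uncertain PHO12), or 5 and 3 adjusted over the list alone. In the iron uptake list 4 of 28 tested members fell (FET3, ENB1, FTR1, SIT1) and 1 rose (HMX1), or 4 and 1 adjusted over the list alone, with the ferroxidase gene FET3 at -1.31 ± 0.14. That list had a median of 0.08, a mean of 0.00434 and a downward direction in camera, which did not pass (adjusted p = 0.878). Calls that ended without 1 library (named by group and replicate number, adjusted p in brackets) were MIG2 without WT untreated 1 (0.0721) or WT perchlorate 1 (0.106) or WT perchlorate 2 (0.117) and HMX1 without WT perchlorate 1 (0.177).

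Transcripts of the translation machinery fell in WT. Of ribosome biogenesis genes, 57 of 73 tested members fell and 0 rose, or 64 and 0 adjusted over the list alone, with a median log2 fold change of -0.55. The cytosolic ribosomal protein list was drawn by name pattern and so also holds the RNase P subunit RPP1. In it 89 of 138 tested members fell and 1 rose (RPL15B), or 121 and 1 adjusted over the list alone, with a median of -0.51. The a mating type and pheromone list fell as well, as 16 of 23 tested members fell and 1 rose (PRM4), or 17 and 1 adjusted over the list alone. The a-factor gene MFA1 was at -1.93 ± 0.17, and FUS1, a membrane protein of cell fusion, at -2.09 ± 0.22. In the P-body and mRNA decay list 3 of 28 tested members fell (DCP1, LSM2, PAT1) and 1 rose (EDC2), or 1 and 1 adjusted over the list alone. In the stress granule list 6 of 28 tested members fell and 2 rose (RIE1, HSP104), or 7 and 2 adjusted over the list alone, with the RNA-binding RIE1 at 0.97 ± 0.17 and the initiation factor TIF4631 at -0.73 ± 0.15. Oxidative stress genes included the peroxiredoxins TSA2 at 2.68 ± 0.25 and PRX1 at 1.56 ± 0.19, and 13 of 32 tested members rose and 1 fell (GND1), or 16 and 2 adjusted over the list alone. Chaperones split, since 9 of 29 tested members rose and 4 fell (HSC82, uncertain SSA2, MGE1, HSP60), or 9 and 4 adjusted over the list alone, with a median of -0.06, a mean of 0.20 and an upward direction in camera, which did not pass (adjusted p = 0.80). The small heat shock protein gene HSP26 rose by 2.86 ± 0.21 and the Hsp70 gene SSA4 by 1.52 ± 0.15. In the autophagy list 14 of 26 tested members rose and 0 fell, or 18 and 0 adjusted over the list alone, with the phagophore protein gene ATG8 at 1.29 ± 0.18. In the unfolded protein response list 5 of 25 tested members rose (INO1, HAC1, uncertain ERV2, ERO1, HRD3) and 0 fell, or 2 and 0 adjusted over the list alone. Calls that ended without 1 library (adjusted p in brackets) were EDC2 without WT perchlorate 1 (0.0925), DCP1 without WT perchlorate 1 (0.119), LSM2 without WT perchlorate 1 (0.283) or WT perchlorate 2 (0.0908), HSP104 without WT perchlorate 1 (0.150), HAC1 without WT perchlorate 2 (0.0807) and ERV2 without WT perchlorate 1 (0.210) or WT perchlorate 2 (0.284).

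By limma with Benjamini-Hochberg adjustment, 1499 of 5664 genes tested changed in WT with perchlorate, 811 higher and 688 lower, and 325 and 71 of these by at least 2-fold. The count fell to 511 without WT perchlorate replicate 1 and to 838 without WT perchlorate replicate 2, rose to 2380 without WT untreated replicate 1, and was 2299 by edgeR on recovered reads. Rises did not outnumber falls with either count test, as edgeR gave 1054 higher and 1245 lower and DESeq2 1089 and 1130.

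In the mutant, perchlorate raised transporters of phosphate, glycerol and sulfate among the genes with the largest changes. STL1 (YDR536W) rose from 340.1 ± 37.3 to 14493 ± 422 normalized reads (mean ± SD, n = 2), a log2 fold change of 5.41 ± 0.10 (SE; adjusted p = 8.03e-09). The sulfate permease gene SUL1 (YBR294W) rose by 4.68 ± 0.19 (adjusted p = 5.02e-07), and GRE1 by 4.27 ± 0.10. The phosphate transporter gene PHO84 (YML123C) rose by 5.50 ± 0.22, uncertain because another annotated transcript overlaps it. FDH1, a formate dehydrogenase, and HSP33, a member of the DJ-1 family, rose by 4.40 ± 0.24 and 4.04 ± 0.23, and both are uncertain because near-identical copies exist. The largest fall was that of MF(ALPHA)2 (YGL089C), an alpha-factor gene, from 3724 ± 1133 to 190.3 ± 68.0 normalized reads. The membrane protein gene INA1 (YLR413W) fell by 2.22 ± 0.09, and the cell wall mannoprotein gene TIP1 (YBR067C) by 1.96 ± 0.10, on the log2 scale.

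In the Msn2/4 list of the mutant 32 of 41 tested members rose and 0 fell, or 34 and 0 adjusted over the list alone, with TKL2 at 3.70 ± 0.17 and NQM1 at 3.56 ± 0.11. With camera 18 of 25 lists passed in the mutant at the preset correlation and none with an estimated one (adjusted p = 0.415 to 0.591 for those 18). In the Hog1 list 17 of 32 tested members rose and 3 fell (HOG1, CRZ1, NHA1), or 19 and 7 adjusted over the list alone. Among sulfur assimilation and methionine genes 27 of 33 tested members rose and 0 fell, or 28 and 0 adjusted over the list alone, with MET2 at 3.58 ± 0.10 and SUL2 at 3.03 ± 0.10. The TCA and glyoxylate list held the isocitrate dehydrogenase gene IDP2 at 2.94 ± 0.10 and the carrier gene SFC1 at 2.83 ± 0.17, and 22 of 28 tested members rose and 1 fell (PYC2), or 23 and 1 adjusted over the list alone. Of respiratory genes, 18 of 40 tested members rose and 1 fell (CYC1), or 19 and 1 adjusted over the list alone, with NDE2 at 2.83 ± 0.17. In the hexose transport list 10 of 15 tested members fell and 2 rose (HXT5, GAL2), or 10 and 2 adjusted over the list alone, with HXT3 at -1.36 ± 0.15. The Gcn4 list gave 1.12 ± 0.09 for the serine enzyme SER33 and 0.96 ± 0.11 for the arginine enzyme CPA1, and 14 of 56 tested members rose and 8 fell, or 14 and 8 adjusted over the list alone, so members went both ways and camera did not pass (adjusted p = 0.312). In the iron uptake list 7 of 27 tested members rose and 3 fell (FRE1, ENB1, FET3), or 7 and 3 adjusted over the list alone, with the mannoprotein gene FIT1 at 2.26 ± 0.17 and an adjusted p of 0.214 in camera. In the autophagy list 15 of 26 tested members rose and 0 fell, or 18 and 0 adjusted over the list alone. Of oxidative stress genes 17 of 32 tested members rose and 2 fell (GND1, TSA1), or 17 and 3 adjusted over the list alone, with TSA2 at 2.32 ± 0.09.

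Ribosomal protein genes fell in the mutant too, as 118 of 138 tested members fell and 0 rose, or 128 and 1 adjusted over the list alone. Of ribosome biogenesis genes 47 of 73 tested members fell and 0 rose, or 54 and 1 adjusted over the list alone. Chaperones of the Hsf1 list split: 15 of 29 tested members fell and 6 rose, or 15 and 6 adjusted over the list alone, with HSP26 at 2.52 ± 0.13. Among unfolded protein response genes 10 of 25 tested members fell and 1 rose (INO1), or 10 and 1 adjusted over the list alone. The ER chaperone gene KAR2 fell by 1.01 ± 0.09 and the mannosyltransferase gene PMT2 by 0.64 ± 0.09, while the riser, INO1, encodes an inositol synthase. The P-body and mRNA decay list held EDC2, a decapping activator, at 0.72 ± 0.09 and PAT1 at -0.47 ± 0.11, and 6 of 27 tested members fell and 1 rose (EDC2), or 4 and 1 adjusted over the list alone. In the stress granule list 11 of 28 tested members fell and 0 rose, or 13 and 0 adjusted over the list alone, with TIF4631 at -0.65 ± 0.10 and the RNA-binding WHI3 at -0.56 ± 0.09. All 4 tested alpha mating type genes fell, with SAG1, the alpha agglutinin gene, at -1.28 ± 0.18.

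A total of 1912 of 5670 genes tested changed in the mutant with perchlorate by limma, 1020 higher and 892 lower, and 315 and 50 of these by at least 2-fold. The responses of both genotypes overlapped: 591 genes rose in both (145 if independent, n1 × n2 / N) and 432 fell in both (108). By contrast, 11 rose in WT and fell in the mutant and 20 did the reverse. The log2 fold changes of 5615 genes tested in both had r = 0.77 and Spearman rho = 0.71 across genes, which are not independent replicates.

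**Figure D2:**
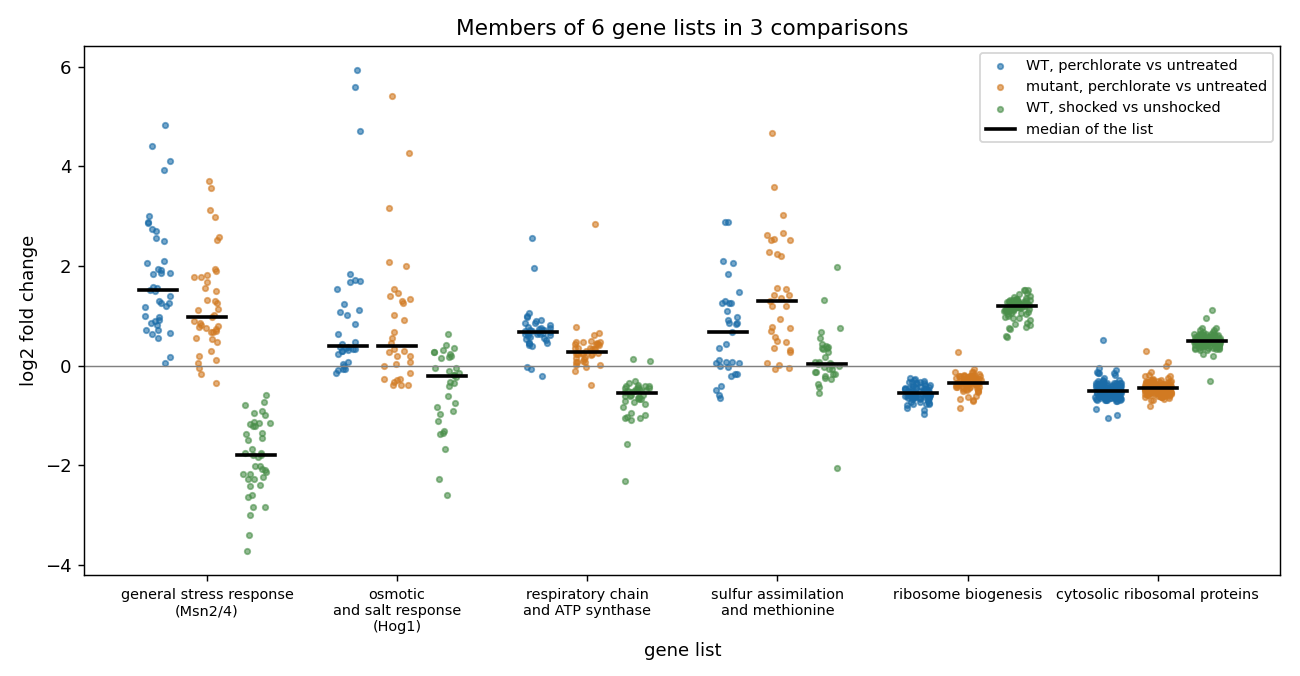
Log2 fold change of each tested member of 6 gene lists in 3 comparisons; each point is 1 gene and each black bar the median of its list. The general stress list has medians of 1.51 in WT with perchlorate, 0.98 in the mutant with perchlorate and -1.79 in shocked against unshocked WT.

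Whether the mutant responded differently to perchlorate was tested as the interaction of genotype and treatment. Amino acid and sulfur genes were among those with a different response. The strains also differed in LEU2 and MET17, enzyme genes of leucine and methionine synthesis. Effects of these markers on the response cannot be told apart from those of the mutations. In the Gcn4 list 17 of 56 tested members had a higher response in the mutant and 0 a lower one (28 and 0 adjusted over the list alone; camera adjusted p = 0.116 with an estimated correlation). HIS4, ARG1 and LEU1 were among them, and HIS4 had fallen by 2.02 ± 0.14 in WT. Between the untreated strains HIS4 and LEU1 were already lower in the mutant, at -2.24 ± 0.15 and -2.13 ± 0.09 log2. ARG3 of the same list was higher there, at 2.50 ± 0.13. The interaction does not tell a different response apart from the effect of a different starting level. In the sulfur list 11 of 33 had a higher response and 0 a lower one (21 and 0 adjusted over the list alone; camera adjusted p = 0.360 with an estimated correlation), including JLP1, MET2, MET3, MET10, MET14 and SUL2. Sulfur genes called between the untreated strains, other than MET17, were lower in the mutant before treatment. DIC1 (YLR348C), the mitochondrial dicarboxylate carrier gene, fell in WT from 3548 ± 301 to 943 ± 23.3 normalized reads and rose in the mutant from 1180.5 ± 72.4 to 1963 ± 39.6 (interaction 2.64 ± 0.14 log2, adjusted p = 1.03e-04). SNO1 (YMR095C), a vitamin B6 gene, went from 60.6 ± 11.1 to 88.4 ± 13.6 in WT and from 39.5 ± 3.59 to 399 ± 118 in the mutant (2.73 ± 0.34, adjusted p = 0.00408). PHO84, uncertain because another transcript overlaps it, had an interaction of 2.86 ± 0.43 (adjusted p = 0.00903).

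Lower responses in the mutant were led by HSP30, a plasma membrane heat shock protein gene, at -3.43 ± 0.68 (adjusted p = 0.0322). OLE1 (YGL055W), the fatty acid desaturase gene, went in WT from 17401 ± 3813 to 33555 ± 2629 normalized reads and in the mutant from 26018 ± 3152 to 16278 ± 1886 (-1.64 ± 0.23, adjusted p = 0.00743). Further interactions were -2.01 ± 0.29 for YER053C-A, -1.92 ± 0.28 for TDA6, -1.71 ± 0.26 for the transcription factor gene STP4, -1.59 ± 0.17 for NCA3 and -1.01 ± 0.16 for URA3. The unfolded protein response list had 3 lower responses, KAR2, ERO1 and LHS1, and 0 higher ones among 25 tested (6 and 0 adjusted over the list alone). Higher responses came in 3 TCA genes (ACO1, IDH2 and IDP2, or 6 higher and 1 lower adjusted over the list alone) and 3 iron genes (FIT1, FTR1 and FET3, or 8 and 0). In the a mating type list 8 of 23 had a higher response (13 adjusted over the list alone). AGA2 was at 2.95 ± 0.51, BAR1 at 2.59 ± 0.18 and MFA1 at 2.42 ± 0.35, but these 3 had only 0 to 50 reads per mutant library. The interaction of MET17, with 0 reads in 3 of 4 WT libraries, was -1.32 ± 1.94 (adjusted p = 0.833). It became -4.20 without WT perchlorate replicate 1 (adjusted p = 1.58e-04) and 1.56 without replicate 2 (adjusted p = 0.0227). Calls that ended without 1 library (adjusted p in brackets) were URA3 without mutant untreated 2 (0.0588) or mutant perchlorate 1 (0.0585), AGA2 without WT perchlorate 1 (0.0915) or mutant perchlorate 1 (0.0708) and HSP30 without WT perchlorate 1 (0.0655) or WT perchlorate 2 (0.114) or mutant untreated 1 (0.106) or mutant perchlorate 2 (0.107) or mutant perchlorate 1 (0.116). By edgeR and DESeq2 AGA2 was not called, nor was HSP30 without the intensity trend or with robust eBayes.

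Over all genes, 144 of 5689 had a different response by limma, 106 higher and 38 lower in the mutant, and 768 had an unadjusted p under 0.05. With camera 14 of 25 lists passed at the preset correlation. With an estimated one no list passed except that of the a mating type (adjusted p = 0.0292), a call with a limit, because AGA2, MFA1, BAR1 and STE2 had 0 to 67 reads per mutant library and little room to fall as they did in WT. The count was 380 without WT untreated replicate 1, where lower responses outnumbered higher ones (177 higher and 203 lower). It was 91 without WT perchlorate replicate 2 or mutant untreated replicate 1, 85 without mutant untreated replicate 2, 76 and 75 without mutant perchlorate replicate 1 and 2, and 225 by DESeq2.

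The comparison of untreated mutant with untreated WT gave the differences between the strains before stress, with mating type and marker genes at its top. MF(ALPHA)1 (YPL187W) had 5.76 ± 1.74 normalized reads in WT and 20393 ± 2096 in the mutant (mean ± SD, n = 2), and the alpha cell receptor gene STE3 (YKL178C) 140.1 ± 20.0 and 4106 ± 246. The a cell receptor gene STE2 was at -7.76 ± 0.16 log2, and in the a mating type list 13 of 23 tested members were lower and 0 higher, or 17 and 0 adjusted over the list alone. Several genes had 0 reads in both untreated mutant libraries. REE1 was at least 295-fold lower, AIF1 at least 159-fold and the siderophore transporter gene ARN2 at least 150.0-fold. AAD6 was at least 135-fold lower and HMRA1, which encodes the mating type protein a1, at least 126-fold. The counts do not show which mating type locus gave the reads assigned to HMRA1. COS8 was also far lower, with a mutant-to-WT ratio of 0.00175 (95% counting interval 0.000477 to 0.00449). COS4 and YCL019W were higher, with ratios of 88.3 (47.8 to 185) and 53.5 (30.4 to 104), both uncertain because near-identical copies exist.

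Beside these, respiratory genes were higher in the untreated mutant. In that list 33 of 40 tested members were higher and 1 lower (COX5B), or 36 and 1 adjusted over the list alone. Camera passed 12 of 25 lists between the untreated strains at the preset correlation and none with an estimated one (adjusted p = 0.550 to 0.956 for those 12). The cytochrome c gene CYC1 was at 3.20 ± 0.10 (adjusted p = 1.02e-05) and the oxidase subunit gene COX5A at 2.28 ± 0.09 (adjusted p = 2.32e-05), while the lower member encodes the alternative subunit. Glycolytic genes were lower: 13 of 24 tested members were lower and 1 higher (ADH2), or 14 and 1 adjusted over the list alone, with the aldolase gene FBA1 at -0.98 ± 0.08. Of cytosolic ribosomal protein genes, 69 of 138 tested members were lower and 1 higher (RPS28B), or 109 and 2 adjusted over the list alone, with a median of -0.33. In the sulfur list 15 of 33 tested members were lower and 1 higher (MET17), or 16 and 2 adjusted over the list alone. The methionine synthase gene MET6 was at -1.28 ± 0.13 and the transporter gene MMP1 at -2.68 ± 0.21, whereas MET17 is missing from WT. The Gcn4 list held ARG3 at 2.50 ± 0.13, HIS4 at -2.24 ± 0.15 and LEU1 at -2.13 ± 0.09, and 18 of 56 tested members were lower and 9 higher, or 26 and 11 adjusted over the list alone. The osmotic gene STL1 was already higher in the untreated mutant, 309 ± 34.2 against 11.2 ± 1.76 normalized reads, with GRE1 at 1.72 ± 0.20. In the Hog1 list 6 of 32 tested members were higher and 2 lower (GRE2, DAK1), or 6 and 2 adjusted over the list alone. In the Msn2/4 list 8 of 41 tested members were higher and 3 lower (HSP26, ALD2, UGP1), or 11 and 3 adjusted over the list alone, with CYC7 at 2.14 ± 0.33. The acid phosphatase gene PHO3 was at -7.26 ± 0.14, and in the phosphate list 8 of 23 tested members were lower and 2 higher (uncertain PHO11, GIT1), or 9 and 2 adjusted over the list alone. In the iron list 10 of 28 tested members were lower and 3 higher (HMX1, CCC2, AKR1), or 10 and 3 adjusted over the list alone, with the heme oxygenase gene HMX1 at 2.86 ± 0.34. In the ergosterol list 10 of 26 tested members were higher and 4 lower (UPC2, ERG3, NCP1, HMG2), or 11 and 4 adjusted over the list alone. In the P-body and mRNA decay list 3 of 28 tested members were lower (EDC3, LSM7, SBP1) and 1 higher (PAT1), or 2 and 0 adjusted over the list alone. Calls that ended without 1 library (adjusted p in brackets) were LSM7 without mutant untreated 2 (0.139) or mutant untreated 1 (0.176), PAT1 without WT untreated 1 (0.0633) or WT untreated 2 (0.0671) or mutant untreated 2 (0.0890) or mutant untreated 1 (0.459) and ADH2 without WT untreated 2 (0.0742).

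With limma 1277 of 5665 genes tested differed between the untreated strains, 621 higher and 656 lower in the mutant, and 233 and 183 by at least 2-fold. Lower calls did not outnumber higher ones without 1 library: the counts were 782 higher and 771 lower without WT untreated replicate 1, 706 and 692 without WT untreated replicate 2, 405 and 350 (755 in all) without mutant untreated replicate 1, and 500 and 352 without mutant untreated replicate 2. Of the 1277 calls, 39 were among 51 genes absent in 1 genotype or on the mating type and marker lists. Without these 51, a choice made after seeing the data, 1229 were called again. That repeat left the values of the other genes as they were, so it cannot test effects of the strain background on them.

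In perchlorate, the mutant differed from WT again in mating type, marker and respiratory genes. CYC1 (YJR048W) was higher by 2.82 ± 0.10 log2 (SE; adjusted p = 5.44e-07) and COX5A (YNL052W) by 1.76 ± 0.13 (adjusted p = 2.58e-05). In the respiratory list 20 of 40 tested members were higher and 2 lower (COX5B, ATP3), or 22 and 2 adjusted over the list alone. In this comparison 13 of 25 lists passed camera at the preset correlation and none with an estimated one (adjusted p = 0.579 to 0.815 for those 13). STL1 reached 14572 ± 389 normalized reads in the mutant and 835 ± 2.14 in WT (mean ± SD, n = 2), a difference of 4.12 ± 0.09 log2. The arginine genes ARG3 and ARG1 were higher by 3.64 ± 0.12 and 2.97 ± 0.11, and in the Gcn4 list 19 of 56 tested members were higher and 6 lower, or 20 and 7 adjusted over the list alone. RDT1 had 0 reads in the mutant and was at least 64.3-fold lower, and PHO3 was at -5.66 ± 0.13 log2. The a cell receptor gene STE2 was at -5.90 ± 0.13 and the alpha cell receptor gene STE3 at 3.30 ± 0.10.

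Some members of the unfolded protein response list and of the Hsf1 chaperone list were lower in the mutant under perchlorate. In the unfolded protein response list 14 of 25 tested members were lower and 0 higher, or 19 and 0 adjusted over the list alone, with EUG1, a disulfide isomerase gene, at -1.08 ± 0.10 and KAR2 at -0.99 ± 0.10. In the Hsf1 list 12 of 29 tested members were lower and 3 higher (HSP10, MDJ1, HSP60), or 14 and 4 adjusted over the list alone. SSA4 was at -1.69 ± 0.11, HSP26 at -1.29 ± 0.19 and the disaggregase gene HSP104 at -0.90 ± 0.14. In the sulfur list 17 of 33 tested members were higher and 2 lower (MMP1, CYS4), or 17 and 2 adjusted over the list alone, with MET17 first and the sulfonate dioxygenase gene JLP1 at 1.69 ± 0.20. Of the TCA list, IDH1 was at 1.36 ± 0.10 and IDP2 at 1.27 ± 0.11, and 10 of 28 tested members were higher and 3 lower (MDH3, FBP1, LSC2), or 12 and 4 adjusted over the list alone. In the glycolysis list 10 of 24 tested members were lower and 2 higher (ADH2, HXK2), or 10 and 2 adjusted over the list alone, with TDH1 at -1.46 ± 0.11 and ADH1 at -1.09 ± 0.17. In the ribosome biogenesis list 13 of 73 tested members were higher and 0 lower, or 5 and 0 adjusted over the list alone, with NOP8 at 0.50 ± 0.11 and a camera adjusted p of 0.815 with an estimated correlation. In the Msn2/4 list 12 of 41 tested members were lower and 4 higher (CYC7, CTT1, HSP31, TKL2), or 13 and 5 adjusted over the list alone. Of oxidative stress genes 8 of 32 tested members were lower and 4 higher (OYE3, GRX1, MCR1, ZWF1), or 9 and 6 adjusted over the list alone, with the glutathione peroxidase gene GPX2 at -1.09 ± 0.10, a median of 0.03, a mean of -0.06 and a downward direction in camera, which did not pass (adjusted p = 0.702). In the stress granule list 7 of 28 tested members were lower and 1 higher (HRP1), or 7 and 1 adjusted over the list alone, with RIE1 at -0.67 ± 0.10. In the P-body and mRNA decay list 4 of 28 tested members were lower (EDC3, DHH1, LSM7, SBP1) and 1 higher (PAT1), or 3 and 0 adjusted over the list alone, with a median of 0.05, a mean of -0.30 and a downward direction in camera, which did not pass (adjusted p = 0.961). In the cell wall list 10 of 36 tested members were lower and 5 higher (PRM5, PIR3, CHS2, SLT2, KDX1), or 11 and 5 adjusted over the list alone, with TIR1 at -3.35 ± 0.21. Calls that ended without 1 library (adjusted p in brackets) were DHH1 without WT perchlorate 1 (0.0749) or mutant perchlorate 2 (0.0633) and LSM7 without WT perchlorate 2 (0.0952) or mutant perchlorate 1 (0.0863).

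Under perchlorate 1818 of 5701 genes tested differed between the strains by limma, 931 higher and 887 lower in the mutant, and 200 and 160 by at least 2-fold. By DESeq2 on recovered reads the balance turned, with 826 higher and 846 lower. The genotype differences overlapped without and with perchlorate, as 482 genes were higher in the mutant in both (101 if independent) and 400 lower in both (102), against 5 and 17 with opposite signs.

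The comparison of shocked with unshocked WT asked what differs in cells that regrew after the shock wave. Ribosome biogenesis genes were higher in the shocked cells and stress genes lower. For shock, rose and fell mean higher and lower than in unshocked cells. All 73 tested ribosome biogenesis genes were higher (73 adjusted over the list alone). For shock, 14 of 25 lists passed camera at the preset correlation and none with an estimated one (adjusted p = 0.417 to 0.661 for those 14). The nucleolar protein gene NSR1 (YGR159C) went from 4124 ± 388 to 11857 ± 568 normalized reads (mean ± SD, n = 2) and RRP12 (YPL012W) was at 1.51 ± 0.13 log2 (SE; adjusted p = 8.75e-04). In the Msn2/4 list 40 of 41 tested members fell and 0 rose, or 40 and 0 adjusted over the list alone, with ALD3 at -3.40 ± 0.11 (adjusted p = 1.15e-04) and TKL2 at -3.73 ± 0.27 (adjusted p = 7.77e-04). HXT5 was at -3.17 ± 0.10, the stationary phase gene SPG4 (YMR107W) at -3.22 ± 0.15 and the eisosome gene FMP45 (YDL222C) at -3.18 ± 0.16 on the log2 scale. Pheromone genes were higher, as 17 of 24 tested members rose and 0 fell, or 17 and 0 adjusted over the list alone. The mating genes FIG1 (YBR040W) and PRM1 (YNL279W) were at 2.84 ± 0.28 and 2.11 ± 0.20.

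Cytosolic ribosomal protein genes were higher in shocked than in unshocked cells. Of 138 tested members 103 were higher and 1 lower (RPL15B), or 125 and 1 adjusted over the list alone, with a median of 0.49. Respiration genes were lower, where 34 of 40 tested members fell and 0 rose, or 38 and 0 adjusted over the list alone, with NDE2 at -2.31 ± 0.14. In the autophagy list 19 of 26 tested members fell and 0 rose, or 21 and 0 adjusted over the list alone, with ATG19 at -1.24 ± 0.11. Of Hsf1 chaperones 13 of 29 tested members fell and 0 rose, or 14 and 0 adjusted over the list alone, with HSP26 at -2.84 ± 0.27 and SSA4 at -2.33 ± 0.20. In the Hog1 list 13 of 32 tested members fell and 2 rose (PTP3, FPS1), or 13 and 3 adjusted over the list alone, with the glycerol dehydrogenase gene GCY1 at -1.68 ± 0.09. Among oxidative stress genes 13 of 32 tested members fell and 1 rose (GPX2), or 13 and 1 adjusted over the list alone, with TSA2 at -1.26 ± 0.12. In the iron list 9 of 29 tested members fell and 1 rose (ISU2), or 10 and 2 adjusted over the list alone, with FIT2 at -1.90 ± 0.28. Amino acid genes of the Gcn4 list included LEU9 at 0.97 ± 0.10 and LYS4 at 0.88 ± 0.08, and 14 of 56 tested members rose and 1 fell (LYS1), or 7 and 0 adjusted over the list alone. In the stress granule list 5 of 28 tested members rose (RBG1, TIF4631, CDC33, BRE5, DED1) and 5 fell (HSP104, RIE1, NAB6, NGR1, KSP1), or 6 and 5 adjusted over the list alone, with HSP104 at -1.61 ± 0.13 and the GTPase gene RBG1 at 1.02 ± 0.09. In the P-body and mRNA decay list 4 of 28 tested members rose (LSM3, CAF20, NAM7, EBS1) and 3 fell (EDC2, EDC1, SBP1), or 4 and 3 adjusted over the list alone. Of the alpha mating type genes, MF(ALPHA)2 rose from 7.20 ± 2.74 to 85.5 ± 84.5 normalized reads (adjusted p = 0.0300), with 158 reads in shocked replicate 2 and 23 in shocked replicate 1. Calls that ended without 1 library (adjusted p in brackets) were EDC2 without WT unshocked 1 (0.0891) or WT unshocked 2 (0.0910), EDC1 without WT unshocked 1 (0.130) or WT unshocked 2 (0.110), SBP1 without WT unshocked 1 (0.101) or WT unshocked 2 (0.0620) or WT shocked 1 (0.0572) or WT shocked 2 (0.0783), RIE1 without WT unshocked 2 (0.0509) and MF(ALPHA)2 without WT unshocked 1 (0.205) or WT unshocked 2 (0.142) or WT shocked 2 (0.0759). MF(ALPHA)2 was also not called without the intensity trend or with robust eBayes.

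The unshocked libraries differed from the untreated WT libraries of the perchlorate set, a comparison across sets chosen after the data were seen and fitted with edgeR on the recovered reads of all libraries. Against untreated WT, 38 of 41 Msn2/4 genes were higher in unshocked cells and 0 lower (median 1.70), against 1 (OM45) higher and 5 (TKL2, PHM7, ALD3, DDR2, HSP31) lower in shocked cells (-0.12). Ribosome biogenesis genes had 73 lower and 0 higher in unshocked cells (median -1.14), and 5 (UTP15, NOG1, NOC4, RRN3, NSR1) lower and 2 (KRR1, NOP7) higher in shocked cells (0.07). For cytosolic ribosomal proteins 119 were lower and 1 (RPL15B) higher in unshocked cells, and 0 were lower and 0 higher in shocked cells. The medians were -0.58 in unshocked and -0.09 in shocked cells. Autophagy genes had 20 higher and 1 (ATG5) lower in unshocked cells, and 2 (ATG17, VPS30) higher and 3 (ATG5, APE3, LAP3) lower in shocked cells. Of respiratory genes, 15 were higher and 0 lower in unshocked cells (median 0.25), and 1 (COX5B) higher and 11 lower in shocked cells (-0.31). Of pheromone genes, 3 (ASG7, STE18, STE4) were higher and 7 lower in unshocked cells, and 13 higher and 0 lower in shocked cells (median 0.48). Of the 4 alpha mating type genes, 0 were higher in unshocked cells and 3 (MF(ALPHA)1, MF(ALPHA)2, SAG1) in shocked cells (median 2.15), where MF(ALPHA)1 had 44 and 111 reads against 7 and 4 in untreated WT. It also had 40 reads in unshocked replicate 2 and 60 in WT perchlorate replicate 2. These 2 and both shocked libraries were the WT libraries that held reads of LEU2 and MET17, from 2 to 52 per gene.

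**Figure D3:**
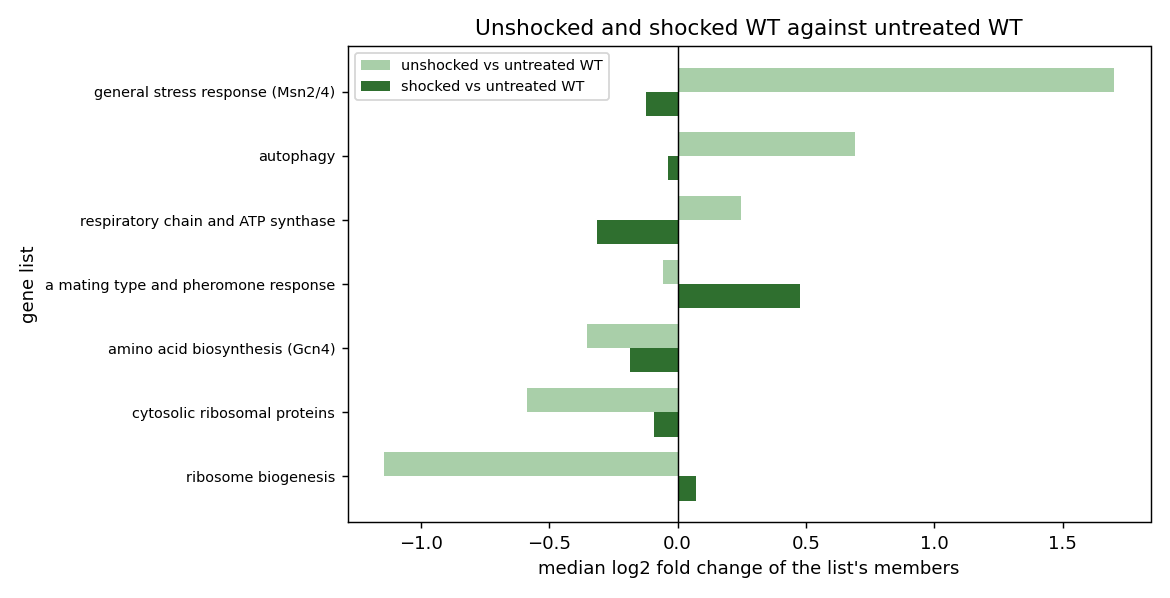
Median log2 fold change of the members of 7 gene lists in unshocked and in shocked WT, each against untreated WT (edgeR on recovered reads); bars start at 0. The general stress list stands at 1.70 in unshocked and -0.12 in shocked cells, and ribosome biogenesis at -1.14 and 0.07.

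By limma, 2007 of 5668 genes tested differed between shocked and unshocked WT, 1026 higher and 981 lower, and 240 and 231 by at least 2-fold. The count fell to 693 without unshocked replicate 1 and to 453 without unshocked replicate 2, and falls outnumbered rises without shocked replicate 1 (1006 higher and 1075 lower) or 2 (752 and 775). By edgeR on recovered reads the count was 2051, and 863 with untreated WT as the control. Of the 863, 160 were also among the 2007 called by limma with the same sign. Shared calls of opposite sign are not in that number. Set beside perchlorate in WT, 459 genes rose with perchlorate and were lower after shock (140 if independent), 409 did the reverse (125), and 7 and 6 moved in the same direction. The log2 fold changes of 5642 genes had r = -0.65 and Spearman rho = -0.62 across genes. The unshocked libraries, which differed from untreated WT, enter this overlap as the control of shock. The overlap therefore does not show that shock reversed the perchlorate response.

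The authors' deposited table gave adjusted p values under 0.05 for 1461 transcripts in WT with perchlorate, 1660 in the mutant with perchlorate, 1354 between untreated strains, 1692 between strains in perchlorate and 1875 for shock. Across genes, the log2 fold changes of the authors' deposited table and those reported here had r between 0.996 and 0.999, and 0 genes called in both had opposite signs.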

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

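The tests of explanations below were chosen only after the results had been seen, whereas the test of a different perchlorate response was planned.

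By the interaction test 144 genes responded to perchlorate differently in the mutant and WT. Among the genes named by size, higher responses in the mutant were those of AGA2 (2.95), PHO84 (2.86), SNO1 (2.73), DIC1 (2.64), BAR1 (2.59) and MFA1 (2.42), and lower ones those of HSP30 (-3.43), YER053C-A (-2.01), TDA6 (-1.92), STP4 (-1.71), OLE1 (-1.64) and NCA3 (-1.59), all as log2 differences between the genotypes. The marker URA3, whose product makes uracil, had a difference of -1.01, and the gene copy that gave its reads was not tested. The values of AGA2, BAR1 and MFA1 rest on 0 to 50 reads per mutant library. PHO84 is uncertain because another transcript overlaps it. Since the strains also differ in mating type genes, LEU2 and MET17, none of these differences can be assigned to the mutations alone.

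The strains differed in mating type genes, LEU2 and MET17 beside the EDC3 and LSM4 mutations. Of the 1277 calls between untreated strains, 39 were of genes absent in 1 genotype or on the mating type and marker lists. A mislabelled EDC3 genotype was excluded, since the highest EDC3 count in a mutant library was 0.537% of the lowest WT count. EDC3 reads do not test the LSM4 mutation, so a library mislabelled in LSM4 alone was not excluded. What stays open is which differences come from the mutations, because 22 tested genes had at most 3 reads in every library of 1 untreated genotype and every mutant library shares that background. Effects of the strain background therefore cannot be told apart from those of the mutations in these libraries, and the mutations named by the design stay open as an untested cause.

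The shock comparison called 2007 genes between shocked and unshocked WT. A difference in library size was excluded, as the shocked libraries held 0.984 times the reads of the unshocked ones. The unshocked libraries standing apart from other untreated WT may account for much of it: 82.7% of the called genes lay farther from untreated WT in unshocked than in shocked cells, with a median distance of 0.64 against 0.22 log2. Over 8 choices of single libraries the share was 67.4 to 74.4% with untreated replicate 1 and 87.9 to 89.9% with untreated replicate 2. The labels do not say whether unshocked and untreated cells were grown together, so shock itself stays open as a cause and was not tested apart from that difference. Exchanged labels of shocked and unshocked libraries cannot be told apart from shock, because the design names 0 genes known to change with shock.

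Of WT libraries, 4 held reads of LEU2 and MET17, which WT lacks. Among them was WT shocked replicate 1 with 5 of LEU2 and 2 of MET17, fewer than the 10 reads set for the test. Its LEU2 share was 71.4% (exact 95% interval 29.0 to 96.3%). In WT perchlorate replicate 2 and WT shocked replicate 2, LEU2 made up 31.1% of 74 and 30.7% of 75 reads of LEU2 and MET17. Both shares lay within the 15.7 to 41.6% of the mutant libraries, untreated and perchlorate-grown together. For both, the adjusted exact binomial p = 1 follows from any share inside that range, so it adds nothing. A small carry-over of mutant reads was therefore not excluded as the source of these LEU2 and MET17 reads. That source was argued against for MF(ALPHA)2 in WT shocked replicate 2, where its reads, less the most in a WT library without LEU2 reads, made up 57.5% of the sum of these and all MF(ALPHA)1 reads, against at most 15.8% in a mutant library (exact binomial p = 3.94e-53, or 1.51e-27 if each molecule gave 2 reads). In WT unshocked replicate 2, where LEU2 was 66.7% of 30 such reads, carry-over cannot be told apart from another source: the adjusted exact binomial p was 0.0294, but 0.268 if each molecule gave 2 reads, and these p values cover counting error only. The source of the MF(ALPHA)2 reads stays open as well, and no biological explanation was tested.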

How the results depend on the processing

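With 2 libraries per group, the number of genes called depended on the test and on single libraries, and the cause was not tested. Untreated WT as the control for shock was chosen after the results were seen, and the other alternatives here were planned. By edgeR on recovered reads 2299 genes changed in WT with perchlorate, and by DESeq2 225 had a different perchlorate response. With the replicate number as a block the counts were 2458 in WT with perchlorate, 2482 between untreated strains, 3183 between strains in perchlorate (1514 higher and 1669 lower, so that the balance turned) and 260 for the interaction. Same-numbered libraries deviated with correlations of 0.14 to 0.58, but 2 pairs per comparison do not show that numbers pair the samples. With a 2-fold minimum the counts were 396 and 365 for perchlorate in WT and mutant, 416 and 360 between strains untreated and in perchlorate, 471 for shock and 89 for the interaction. At that minimum 222 calls were shared by both genotypes with perchlorate, 158 were opposite between WT perchlorate and shock, and 237 were shared by the genotype comparisons. With untreated WT as the control, shock called 863 genes by edgeR, against 2051 by edgeR with unshocked WT. Leaving out 1 library, where the lone library is assumed to vary like the other groups, gave 511 to 2380 genes in WT with perchlorate, 1579 to 1948 in the mutant, 755 to 1553 between untreated strains, 1370 to 1490 between strains in perchlorate, 453 to 2081 for shock and 75 to 380 for the interaction. Signs changed for genes that had not passed: LSM4 between untreated strains (-0.27 to 0.11, the latter without WT untreated replicate 2), LYS2 in the same comparison (-0.0460 to 0.0186 without mutant untreated replicate 1 and 2, and 0.01 without WT untreated replicate 2), and MET17 in the interaction (-4.20 to 1.56, without WT perchlorate replicate 1 and 2). Over the named genes 6189 of 6481 alternative fits gave the same call, 275 lost it, 13 gained it and 4 changed sign. Over 149 list tests, median-of-ratios rescaling ended 0 of the calls. An estimated correlation ended 85 and left 1, that of the a mating type list in the interaction. That test had 2 residual degrees of freedom in each comparison and 4 in the interaction. With so few, an ended call does not show that a list was unchanged.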

Other observations

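The comparison of unshocked with untreated WT was chosen only after the results had been seen. It used edgeR on recovered reads across sets, and 2773 genes differed, 1373 higher and 1400 lower in unshocked cells. Iron uptake genes, which the Aft1 factor controls, were higher in unshocked cells in 13 of 29 and lower in 1 (FTR1). Ergosterol synthesis genes were lower in 19 of 26 and higher in 3 (ERG28, HMG2, ERG20). Amino acid genes of the Gcn4 list were lower in 32 of 56 and higher in 4 (uncertain SER3, ARG4, HIS4, GLN1). Proteasome genes were higher in 8 of 34 and lower in 0, and chaperone genes of the Hsf1 list were higher in 13 of 29 and lower in 6. In shocked against untreated WT the same lists had 2 (ENB1, FRE6) higher and 2 (FTR1, FET5) lower for iron, 0 and 7 for ergosterol, 0 and 14 for amino acid genes, 1 (RPN11) and 2 (PRE4, PRE2) for the proteasome, and 1 (CDC37) and 7 for chaperones (median -0.31, against 0.32 in unshocked cells).

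The osmotic transporter gene STL1 had 297 and 366 reads in the untreated mutant libraries, 10 and 11 in untreated WT, and 7 to 30 in unshocked and shocked WT. In perchlorate it had 14586 and 15371 reads in the mutant and 723 and 914 in WT. URA3, which growth without uracil needs, had 8489 and 8675 reads in the untreated mutant and 2071 and 2468 in untreated WT. Every WT library held reads of URA3, from 2071 to 4198, and the gene copy that gave them was not tested.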
